A study of Mus musculus with 27 samples.

How the data were processed

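RNA was measured by bulk sequencing in 27 libraries from the hearts of 14 mice, 7 days after infarction. Each library came from the infarct or from remote myocardium of the same heart, and 13 mice gave both. The deposited table holds whole-number counts for 27304 genes, the unit taken from the values themselves. Per the submitters' processing notes, kallisto 0.48.0 and genome build GRCm39 were used. The notes do not say how transcript estimates became counts per gene, nor which annotation release or filter was applied, so no coordinates are given. Total counts per library ran from 14255456 to 42566498, and 21658 genes had at least 1 count.

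Groups came from the sample titles and labels. The remote library of mouse 9179 is titled CKD while its treatment label says control. It was placed in the CKD group, like the infarct library of the same mouse, and the comparisons that use it were repeated without it. With it counted as control, the gene tests of those comparisons and the remote scores were repeated. The list tests and the region comparison in control mice were not repeated in that way. All 27 table columns were matched to a sample. The symbols of 27 genes had turned into dates and were renamed from their Ensembl IDs, while 479 entries that share a symbol were kept apart by ID. All 353 genes of 33 lists were found, 4 of them under an older symbol, such as Arntl for Bmal1.

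Genes were filtered with filterByExpr, scaled with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CKD was compared with control within each region from the libraries of that region alone. The difference between those effects and the 2 comparisons of infarct with remote tissue came from a fit of all 27 libraries with 4 group means. Standard errors of log2 fold changes were derived from the fold change and its F value. Gene lists were tested against all other genes with camera of limma 3.58.1, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The sign of a list test, the list's median and its mean are from that log2 CPM scale. A score of a list in a library is the mean log2 CPM of its members. Scores were compared by exact two-sided permutation tests, adjusted together over 14 tests. These score tests were chosen after the data were seen.

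The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, per comparison, called genes with a mean of at least 1 CPM, the 10 with the smallest p in each direction. It adds up to 3 called members of each list, or the 2 members with the smallest p where none was called, and always Apoe, Nppa, Nppb, Myh6, Myh7 and Col1a1. The text prints a selection of these. Ccr2 in remote tissue falls outside the rule and was named after its values were seen.

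Alternatives were DESeq2 size factors, upper-quartile scaling, no filter on low counts, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom with sample weights, a fit of all 27 libraries, the cardiomyocyte score as a covariate, leaving out each library in turn, camera with an estimated correlation, and fry. As alternatives, the fit of all 27 libraries, the covariate and leaving out each library were run only for CKD against control within a region. Fits without the remote library of control mouse 9180, without the infarct libraries of CKD mice 9172 and 9179, and with the covariate while leaving out 9180 were added after the data were seen. Infarct and remote libraries of a mouse are paired by design. Residuals of the 13 pairs, after group means were removed, correlated at -0.10 to 0.40 with a median of 0.17, against a median of -0.02 for other mice. With mouse as a replicate block, 9764 genes instead of 9437 separated infarct from remote tissue in control mice. No library pair of a group was a technical duplicate, since the lowest chi-square per degree of freedom was 9.52 over 79 pairs.

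The gene tests were tested on simulated data with the sample sizes and spread of these groups, in which 200 genes were changed. At 1.5-fold, 2-fold and 4-fold, the CKD comparison recovered 44.8%, 77.6% and 98.4% in remote myocardium. In infarct tissue it recovered 16.4%, 58.2% and 98.5%. The difference of the effects recovered 5.97%, 47.8% and 87.9%. The region comparison recovered 34.3%, 68.7% and 95.5% in control mice and 44.8%, 74.6% and 92.4% in CKD mice. Unchanged genes called numbered 2, 11, 5, 6 and 6 in the same order. A list of 20 raised genes was called in all 5 comparisons and a list of 20 unchanged genes in none. Simulated genes were drawn independently of each other, and no simulated library lay far from its group by design. False calls of lists with correlated members, and of genes that move together between libraries, were therefore not tested. Regrouped real libraries called up to 324 genes in remote and 2515 in infarct tissue, though only 1 and 2 of the drawn splits called any.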

Results

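Heart tissue was taken 7 days after myocardial infarction from male ApoE-deficient mice on a C57BL/6J background, which had eaten a western diet for 4 weeks. In the chronic kidney disease (CKD) group, kidney damage was induced by adenine in the diet, 0.3% for 10 days and then 0.15% for 11 days, 4 of them before and 7 after the infarction. Bulk RNA sequencing covered remote myocardium of 6 control and 8 CKD mice and infarct tissue of 6 control and 7 CKD mice. Counts per gene were summed in 27 libraries, whose totals ran from 14255456 to 42566498 counts. Apoe, the gene these mice lack, still gave 11.5 to 21.4 CPM in the 14 remote libraries and 12.6 to 44.8 CPM in the 13 infarct libraries. Its level did not differ detectably by diet (log2 fold change 0.18, adjusted p = 0.655 in remote and -0.22, adjusted p = 0.604 in infarct tissue).

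The regions differed in makeup, and 2 libraries, 1 of them labelled infarct and 1 remote, lay far from their group. Cardiomyocyte score, the mean log2 CPM of 12 contractile and metabolic genes of heart muscle, averaged 12.01 ± 0.41 (SD, n = 6) in control remote and 9.76 ± 1.19 (n = 6) in control infarct tissue. The infarct library of CKD mouse 9179 had a score of 12.30, Col1a1 at 63.9 CPM and Postn at 15.2 CPM, within or below the range of remote libraries. In the remote library of control mouse 9180 the score was 11.21, with Col1a1 at 4355 CPM and Nppa, the atrial natriuretic peptide gene, at 2036 CPM. The infarct library of CKD mouse 9172 had a score of 12.05, with Col1a1 at 1494 CPM.

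**Figure D1:**
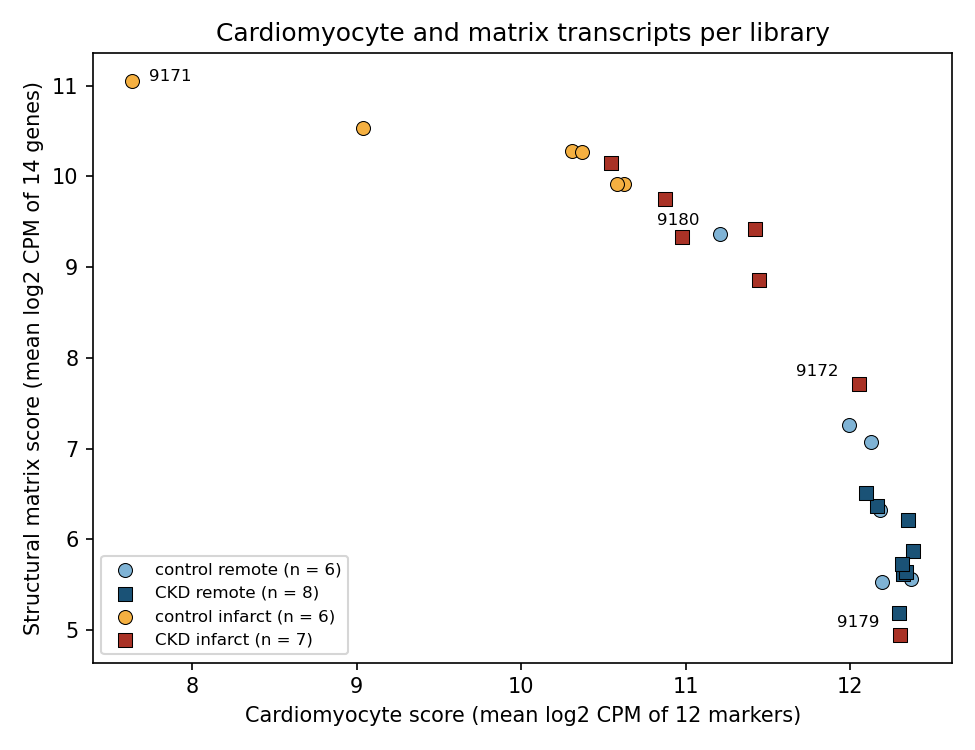
Cardiomyocyte score against structural matrix score, both as mean log2 CPM of the list's genes, with a point per library and a colour per group. The infarct library of CKD mouse 9179 lies at 12.30 and 4.95, among the remote libraries, and the remote library of control mouse 9180 at 11.21 and 9.37, towards the infarct libraries.

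The first comparison asked how CKD changes myocardium away from the infarct. MHC class II transcripts, which serve antigen presentation to T helper cells, fell as a list in CKD remote myocardium, and the list of monocyte and neutrophil markers was called higher. The MHC class II list had 7 of 7 members below control with a median log2 fold change of -0.99 (camera adjusted p = 1.23e-09; adjusted p = 0.254 with an estimated correlation). Its score was 4.21 ± 0.45 (SD, n = 8) in CKD against 5.14 ± 0.50 (n = 6) in control mice (exact permutation p = 0.00266, adjusted p = 0.0163). The monocyte and neutrophil list had a median of 0.82 (adjusted p = 1.63e-04; adjusted p = 0.348 with an estimated correlation), and its score was 0.81 ± 0.46 (n = 8) against -0.06 ± 0.44 (n = 6; exact permutation p = 0.00566, adjusted p = 0.0198). With the remote library of mouse 9179 read as control, as its treatment label has it, the exact permutation p was 0.0140 and 0.0641 for these scores. Without the remote library of control mouse 9180, their differences were -0.76 and 0.997 (exact permutation p = 0.0101 and 0.00233), against -0.93 and 0.86 with all libraries. Haemoglobin and other erythroid transcripts also fell as a list, with a median of -1.55 (adjusted p = 1.10e-04; adjusted p = 0.348 with an estimated correlation), while the exact test of their score gave an adjusted p = 0.0524. Mesothelial markers, of the cells that cover the heart, fell with a median of -1.60 (adjusted p = 1.53e-05; adjusted p = 0.254 with an estimated correlation).

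**Figure D2:**
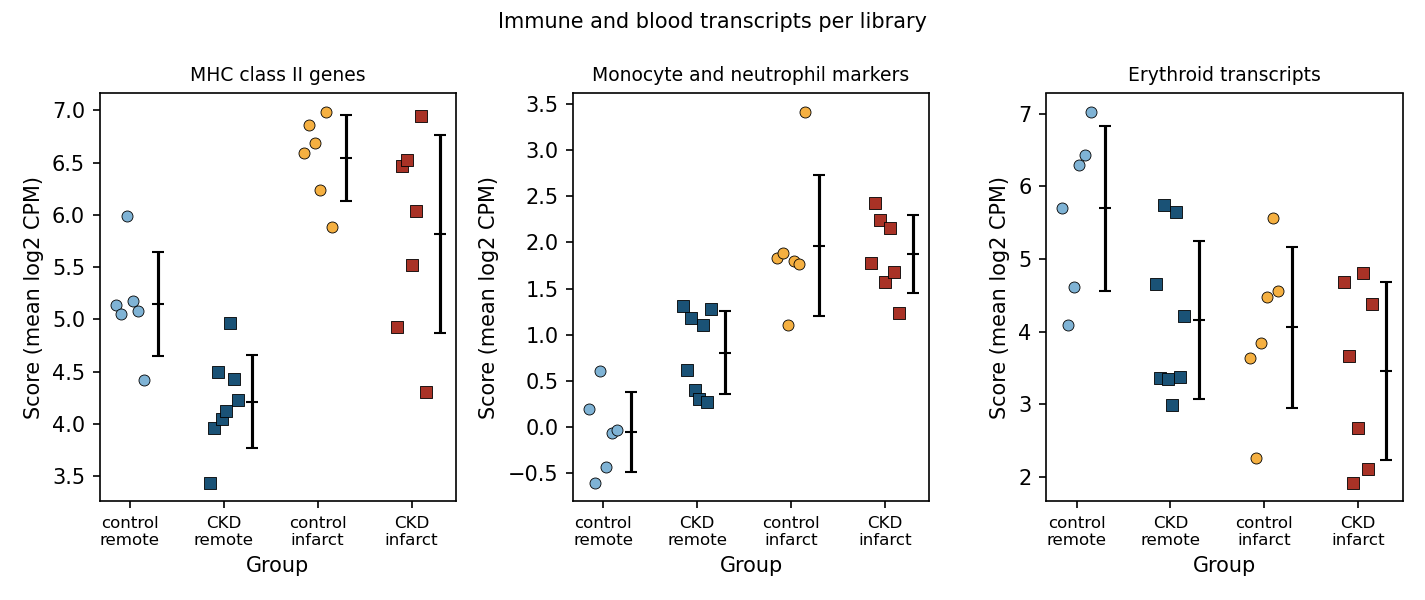
Scores of MHC class II, monocyte and neutrophil, and erythroid transcripts in log2 CPM, with a point per library and the mean and SD of each of the 4 groups. In remote myocardium the MHC class II score averaged 4.21 in CKD and 5.14 in control mice, and the monocyte and neutrophil score 0.81 and -0.06.

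Single members of these lists did not pass the test over all genes. Adjusted over the list alone, 7 of 7 MHC class II genes were lower, and 5 of 9 monocyte and neutrophil genes were higher and 1 lower. S100a8 and S100a9, calcium-binding proteins abundant in neutrophils, had log2 fold changes of 2.15 ± 0.42 (SE) and 1.83 ± 0.41 with adjusted p = 0.116 and 0.182 over all genes. The lower member was Ccr2, a chemokine receptor of inflammatory monocytes, at -1.02 (adjusted p = 0.321), and at -0.43 without control mouse 9180. Ciita, the transcriptional activator of MHC class II genes, stood at -0.82 ± 0.19 (adjusted p = 0.207), and H2-DMb1 at -1.08 ± 0.25 (adjusted p = 0.232). Of erythroid and mesothelial genes, 5 of 5 and 2 of 6 were lower when adjusted over the list alone. Hba-a2, an alpha globin gene, was at -1.45 (adjusted p = 0.346), and Upk1b, a mesothelial marker, at -1.57 (adjusted p = 0.272).

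Over all 13902 genes tested, edgeR called 3 in remote myocardium, all lower in CKD. Angptl7, which encodes a secreted angiopoietin-like protein (ENSMUSG00000028989), fell from 6.80 ± 2.36 CPM (SD, n = 6) to 2.20 ± 0.46 CPM (n = 8), a log2 fold change of -1.53 ± 0.20 (SE, adjusted p = 0.0128). Cd83, a surface protein of mature dendritic cells (ENSMUSG00000015396), fell from 6.91 ± 2.21 to 3.25 ± 0.56 CPM (-0.99 ± 0.15, adjusted p = 0.0429). Aqp8, a water channel (ENSMUSG00000030762), fell from 5.62 ± 1.35 to 2.03 ± 0.75 CPM (-1.38 ± 0.22, adjusted p = 0.0485). At an unadjusted p under 0.05 there were 1626 genes, DESeq2 called 97, 37 higher and 60 lower, and limma-voom 5, all lower. The count was 1 without control mouse 9170, 9171 or 9180 or CKD mouse 9172, 9175, 9177 or 9178, 5 without CKD mouse 9179 and 6 without CKD mouse 9174. Angptl7 passed in each of the 14 fits that left out 1 library, with adjusted p up to 0.0494, Cd83 in 5 and Aqp8 in 3 of them. None of the 3 passed in the fit of all 27 libraries, with the cardiomyocyte score as a covariate (0 genes, 1137 at an unadjusted p under 0.05) or with the conflicting label of mouse 9179 read as control.

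Other lists were called in remote myocardium, several with smaller medians without the control library of mouse 9180. In all, 13 lists were called, 5 higher and 8 lower, and without that library again 13, 5 higher and 8 lower, of which 11 were called in both. Structural matrix genes fell with a median of -0.83 (adjusted p = 6.33e-06) and activated fibroblast markers with -1.19 (adjusted p = 8.59e-05), both with an adjusted p = 0.354 with an estimated correlation. Without the library of mouse 9180 these medians were -0.44 (adjusted p = 3.62e-04) and -0.40 (adjusted p = 0.00417), and both lists were still called. Of their members, 13 of 13 matrix and 10 of 12 activated fibroblast genes were lower when adjusted over the list alone, and none over all genes. Col1a1, a fibrillar collagen gene, stood at -2.23 ± 0.61 (adjusted p = 0.272) and Cthrc1, a marker of activated fibroblasts, at -4.91 ± 1.22 (adjusted p = 0.236). Without mouse 9180 they were at -0.96 ± 0.38 and -1.82 ± 0.78 (adjusted p = 0.533 and 0.553). Oxidative phosphorylation genes rose by a median of 0.23 (adjusted p = 1.53e-05) and cardiomyocyte markers by 0.26 (adjusted p = 1.39e-04), with adjusted p = 0.354 with an estimated correlation for both. Without the library of mouse 9180 they were still called, at 0.06 (adjusted p = 0.00401) and 0.10 (adjusted p = 0.0365). Adjusted over the list alone, 0 of 15 and 1 of 12 of their members were higher. Resting fibroblast, osteochondrogenic, cardiomyocyte stress, ion channel and glycolysis lists were called at -0.30, -0.60, -0.54, 0.21 and 0.09, with adjusted p = 0.254 to 0.354 with an estimated correlation. Without mouse 9180, the stress (adjusted p = 0.0884) and ion channel lists (adjusted p = 0.122) were no longer called, the osteochondrogenic median was -0.29 and the glycolysis median 0.17, fatty acid oxidation genes turned from 0.11 to -0.13 and were called lower (adjusted p = 0.00401), and cytokines were called higher at 0.31 (adjusted p = 0.0317). With the cardiomyocyte score as a covariate the matrix (adjusted p = 0.606), activated fibroblast (0.868) and oxidative phosphorylation lists (0.905) were not called, whereas the MHC class II list stayed at -0.68 and the monocyte and neutrophil list at 0.87. In that fit the fatty acid oxidation (-0.34, adjusted p = 2.75e-07), macrophage (0.25, adjusted p = 0.00373) and interferon lists (0.26, adjusted p = 9.44e-05) turned in sign and were called. Natriuretic peptide genes Nppa (-1.82, adjusted p = 0.355) and Nppb (-0.49, adjusted p = 0.643) and the myosin genes Myh6 (0.21, adjusted p = 0.677) and Myh7 (-0.15, adjusted p = 0.623) did not pass. Without mouse 9180, Nppa was at -0.36, Nppb at -0.19 and Myh6 at 0.06.

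The second comparison asked how CKD changes the infarct itself. Infarct tissue of CKD mice held more transcripts of heart muscle and mitochondria and fewer of scar matrix than that of control mice. All 15 oxidative phosphorylation genes rose over all genes and over the list alone, with a median log2 fold change of 1.41 (adjusted p = 1.74e-07; adjusted p = 0.713 with an estimated correlation). Examples are Ndufb8 of complex I (1.42 ± 0.36 SE), Sdha of complex II (1.16 ± 0.29) and Uqcrc2 of complex III (1.09 ± 0.28), each with an adjusted p = 0.0345. Mitochondrially encoded protein genes made up 11.9 ± 5.03% of counts (SD, n = 7) in CKD and 4.98 ± 2.24% (n = 6) in control infarcts (exact permutation p = 0.00350, adjusted p = 0.0163). The difference of 6.90 percentage points was 4.09 without the infarct libraries of CKD mice 9172 and 9179 (exact permutation p = 0.00433). Fatty acid oxidation genes rose in 11 of 15 cases over all genes, and in 12 adjusted over the list alone, with a median of 1.31 (adjusted p = 3.17e-05; adjusted p = 0.713 with an estimated correlation). They included Acadl (1.26 ± 0.34, adjusted p = 0.0345) and Acadm (1.39 ± 0.39, adjusted p = 0.0348), which act on long and medium acyl chains, and the carnitine carrier Slc25a20 (1.10 ± 0.29).

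Cardiomyocyte markers rose in 5 of 12 cases over all genes and in 11 adjusted over the list alone, with a median of 1.55 (adjusted p = 3.17e-05; adjusted p = 0.713 with an estimated correlation). Tnnt2, cardiac troponin T, rose by 1.44 ± 0.39 (SE, adjusted p = 0.0345), and the calcium release channel Ryr2 and calcium pump Atp2a2 by 1.29 and 1.34 (adjusted p = 0.0368 and 0.0399). Myh6 averaged 16266 ± 5603 CPM (SD, n = 7) against 6613 ± 4034 CPM (n = 6) and just missed the threshold (1.62 ± 0.55, adjusted p = 0.0512). The cardiomyocyte score was 11.37 ± 0.64 (n = 7) against 9.76 ± 1.19 (n = 6; exact permutation p = 0.00233, adjusted p = 0.0163). Ion channel and coupling genes rose in 4 of 10 cases, and in 10 adjusted over the list alone (median 1.22, adjusted p = 9.33e-05; adjusted p = 0.713 with an estimated correlation), among them the potassium channel Kcnq1 (1.31) and the pacemaker channel Hcn4 (2.02). Glycolysis genes rose in 6 of 11 cases, with 7 higher and 1 lower adjusted over the list alone (median 0.56, adjusted p = 0.0201; adjusted p = 0.713 with an estimated correlation), among them Tpi1 (0.86), Gapdh (0.97) and Pkm (0.60).

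Structural matrix genes fell as a list in CKD infarcts, with 14 of 14 members below control and a median of -1.75 (adjusted p = 6.46e-04; adjusted p = 0.713 with an estimated correlation). Only Eln, elastin, passed over all genes (-2.07 ± 0.65, adjusted p = 0.0419), and 0 passed adjusted over the list alone. Col1a1 averaged 5750 ± 4816 CPM (SD, n = 7) against 15838 ± 6614 CPM (n = 6), with an adjusted p = 0.182. Activated fibroblast markers fell in 3 of 12 cases, and in 3 adjusted over the list alone, with a median of -1.72 (adjusted p = 0.00317; adjusted p = 0.713 with an estimated correlation). These were Acta2, smooth muscle actin of myofibroblasts (-1.13, adjusted p = 0.0345), Fap (-0.92, adjusted p = 0.0411) and Comp (-2.07, adjusted p = 0.0477). Cell cycle genes (median -0.88, adjusted p = 0.0476) and osteochondrogenic genes (-1.33, adjusted p = 0.0489) fell as lists, both with adjusted p = 0.713 with an estimated correlation. Of their members, 0 and 2 were lower over all genes, and 0 and 4 when adjusted over the list alone. Without the infarct libraries of CKD mice 9172 and 9179 these 2 lists were not called (adjusted p = 0.477 and 0.106), and the matrix and activated fibroblast medians were -0.85 and -0.81.

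**Figure D3:**
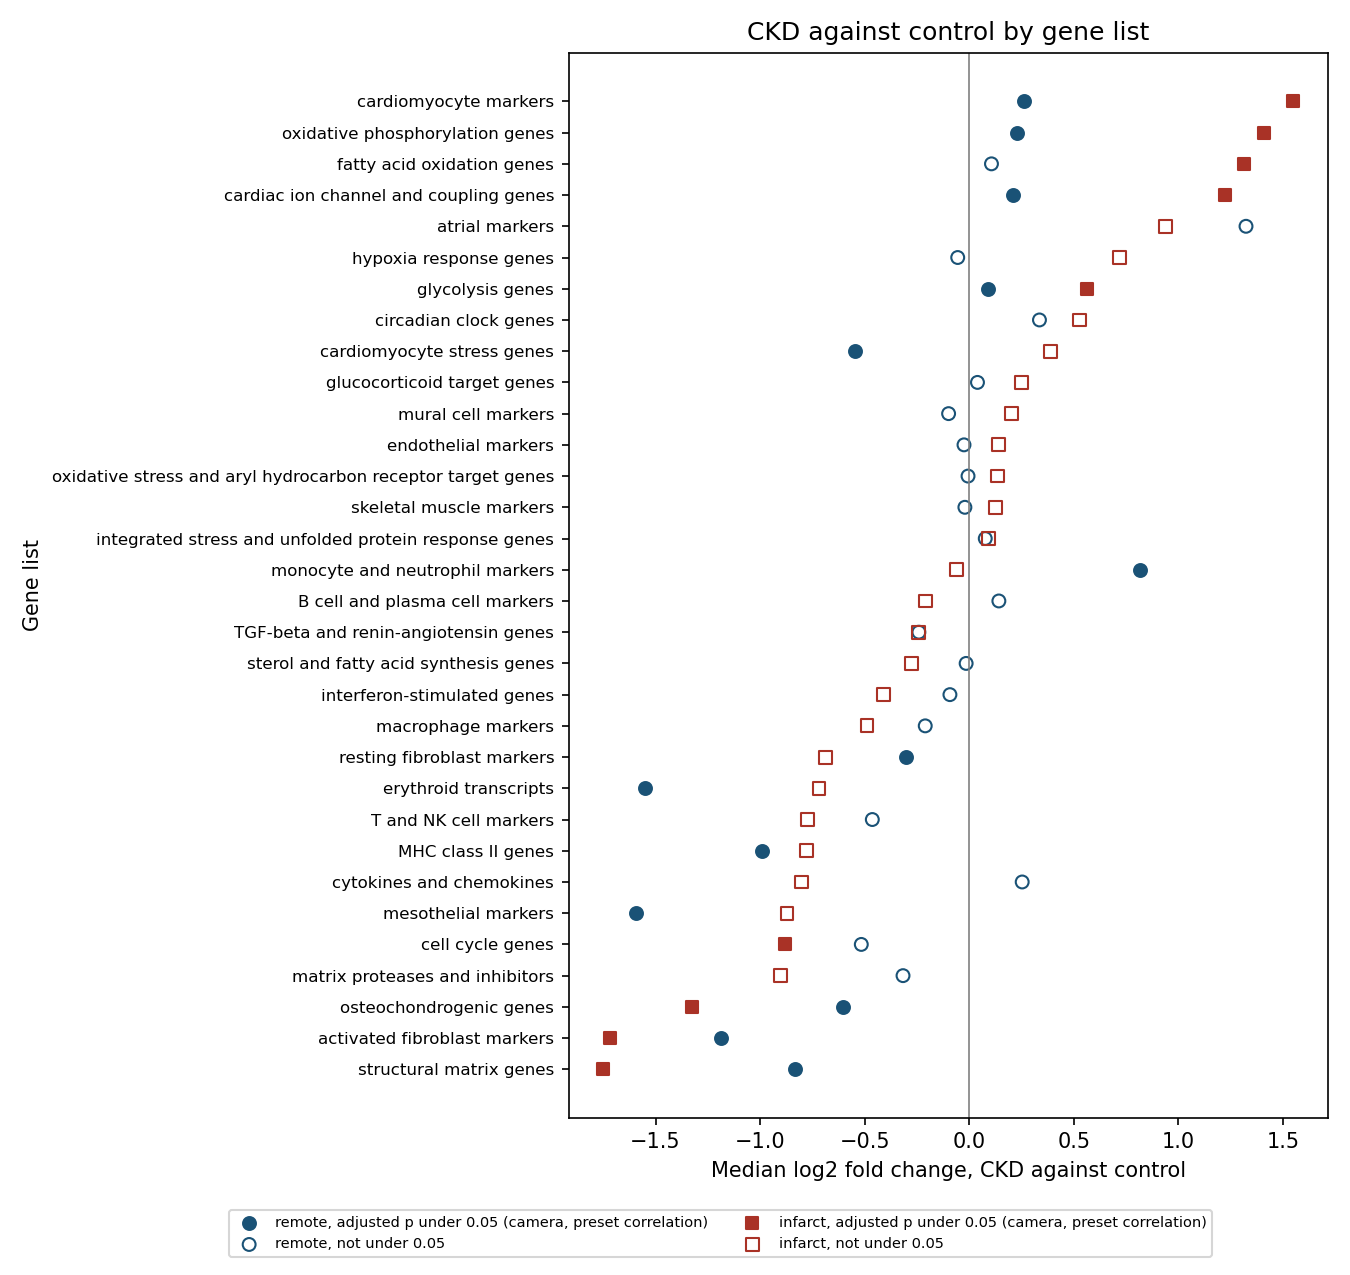
Median log2 fold change of the 32 gene lists tested in both comparisons of CKD with control in remote and infarct tissue, with filled points for lists called at an adjusted p under 0.05 (camera, preset correlation). Oxidative phosphorylation genes lie at 0.23 in remote and 1.41 in infarct tissue, and MHC class II genes at -0.99 and -0.78.

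By gene, edgeR called 2908 of 14358 genes in infarct tissue, 1883 higher and 1025 lower in CKD. Among the higher genes with the smallest p were Msrb1, a methionine sulfoxide reductase (0.67 ± 0.11 SE), Hand2, a cardiac transcription factor (1.04 ± 0.19), and Etfrf1 (1.10 ± 0.21). Among the lower ones were Adamts6, a secreted metalloprotease (-1.09 ± 0.16), Spsb1 (-0.72 ± 0.11), Pkd1, polycystin 1 (-0.85 ± 0.14), and Boc, a hedgehog co-receptor (-1.27 ± 0.21). All 7 had an adjusted p = 0.0345, the lowest value, which 1181 genes shared. The calls therefore lay close to the threshold: the count was 0 without control mouse 9171, 9182 or 9183 or CKD mouse 9172 or 9177, with 4476 to 5311 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.0527 to 0.0837. Without CKD mice 9172 and 9179 together it was also 0, with 4064 at an unadjusted p under 0.05. It was 1644 without CKD mouse 9179, 1742 without 9176, 4651 without 9175 and 1898 without control mouse 9180. With the cardiomyocyte score as a covariate, edgeR called 0 genes (581 at an unadjusted p under 0.05), and of the lists above only oxidative phosphorylation (0.23, adjusted p = 3.35e-05) and glycolysis genes (0.24, adjusted p = 0.00311) were called. Without a covariate DESeq2 called 4557 genes and limma-voom 2367. Nppa (0.11, adjusted p = 0.909), Nppb (0.47, adjusted p = 0.474) and Myh7 (0.57, adjusted p = 0.360) did not pass.

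The third comparison asked whether the effect of CKD differed between infarct and remote tissue. As lists, energy metabolism and heart muscle transcripts had a more positive CKD effect in infarct tissue, and monocyte and neutrophil markers a more negative one. The difference had a median of 1.17 for oxidative phosphorylation (adjusted p = 4.58e-09), 1.21 for fatty acid oxidation (adjusted p = 1.25e-06), 1.32 for cardiomyocyte (adjusted p = 2.96e-06) and 0.84 for ion channel genes (adjusted p = 2.60e-04). The monocyte and neutrophil list had a median of -1.29 (adjusted p = 0.00306). All 5 lists had an adjusted p = 0.528 with an estimated correlation. Adjusted over the list alone, 15 of 15, 12 of 15, 10 of 12 and 7 of 10 members of the first 4 lists were higher and 6 of 12 of the last were lower, with 0 over all genes. Examples are Ndufb8 (1.24 ± 0.39 SE), the fatty acid oxidation gene Acadl (1.22 ± 0.37) and S100a8 (-2.48 ± 0.74), none of which passed (adjusted p = 0.165 for each). In the infarct library of control mouse 9184, S100a8 (22.8 CPM) and the monocyte and neutrophil score (3.42) were the highest of all infarct libraries. Without that library the infarct difference of this score was 0.19 instead of -0.10, against 0.86 in remote tissue. The list test of the difference was not repeated without it. The MHC class II list did not differ detectably between regions (0.18, adjusted p = 0.699), but was called at 0.66 (adjusted p = 0.00286) without the infarct libraries of CKD mice 9172 and 9179.

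Glycolysis genes (0.50, adjusted p = 0.00849), hypoxia response genes (0.79, adjusted p = 0.0425) and endothelial markers (0.25, adjusted p = 0.0480) had a more positive effect in infarct tissue, and cytokines (-0.82, adjusted p = 0.00849) and structural matrix genes (-0.71, adjusted p = 0.0477) a more negative one, all with adjusted p = 0.528 to 0.832 with an estimated correlation. Adjusted over the list alone, 4 glycolysis and 3 hypoxia genes were higher and no member of the other 3 lists passed. The matrix list was negative on the log2 CPM scale of the list test while 11 of its 14 members had positive fitted fold changes. Without the infarct libraries of mice 9172 and 9179 the matrix list was at 0.15 (adjusted p = 0.865), and the cytokine (adjusted p = 0.113), hypoxia (0.0684) and endothelial lists (0.375) were not called. Without the remote library of control mouse 9180 the glycolysis (adjusted p = 0.0584), hypoxia (0.0731) and endothelial lists (0.0960) were not called, the matrix median was -1.21, and without the remote library of mouse 9179 the endothelial list was not called (adjusted p = 0.101). By gene, edgeR called 0 of 14770, with 2787 at an unadjusted p under 0.05, while DESeq2 called 600 and limma-voom 6. With mouse as a replicate block edgeR also called 0, with 2570 at an unadjusted p under 0.05.

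Infarct and remote tissue were then compared within each diet to describe the lesion. In control mice, infarct tissue had gained matrix, fibroblast and immune transcripts and lost those of heart muscle, energy metabolism and endothelium. Structural matrix genes rose in 14 of 14 cases (median 3.40, adjusted p = 1.49e-05; adjusted p = 0.440 to 0.470 with an estimated correlation for this and each other list called in control mice), with Col5a1 at 2.91 ± 0.53 (SE) and Eln at 3.33 ± 0.67. Activated fibroblast markers rose in 10 of 12 cases (3.46), monocyte and neutrophil markers in 11 of 12 (2.16; Csf3r, a neutrophil growth factor receptor, 2.30), T and NK cell markers in 8 of 9 (2.13), cytokines in 13 of 14 (2.01; Il1b 3.20), MHC class II genes in 7 of 7 (1.45) and interferon-stimulated genes in 10 of 13 (median 0.998). Macrophage markers rose in 9 of 12 cases and fell in 2 (1.70; C1qa 1.74). Oxidative phosphorylation genes fell in 15 of 15 cases (-2.15; Uqcrc1 -2.26), fatty acid oxidation genes in 14 of 15 (-2.30; Cpt2 -2.20), cardiomyocyte markers in 12 of 12 (-2.35; Myh6 -2.40), ion channel genes in 9 of 10 (-1.53; Hcn4 -2.95) and endothelial markers in 10 of 10 (-0.79; Kdr, the main VEGF receptor, -1.52).

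In total 16 lists were called in control mice, 10 higher and 6 lower, and 0 with an estimated correlation, while fry, which asks whether a list moves on balance in a direction, called 25. Adjusted over the list alone, the counts given above were the same apart from 15 of 15 for fatty acid oxidation. The lists not yet named were matrix proteases and inhibitors (1.48; Mmp2, a gelatinase, 2.01) and osteochondrogenic genes (2.71; Runx2, a bone transcription factor, 2.54), which rose, and hypoxia response genes (-0.95; Vegfa -1.78), which fell and were not called without the remote library of mouse 9180 (adjusted p = 0.0545). By gene, edgeR called 9437 of 14770, 4528 higher and 4909 lower, and with mouse as a replicate block 9764. Those with the smallest p included Metrn (-1.57 ± 0.18) and Mrps34, of the mitochondrial ribosome (-1.40 ± 0.16), among lower genes and Bmper, a BMP regulator (2.14 ± 0.25), and Il1r1, the interleukin 1 receptor (1.80 ± 0.23), among higher ones, each with an adjusted p = 9.45e-06. Nppb, Myh7 and Apoe (0.34, adjusted p = 0.255) did not pass, nor did Nppa (1.68, adjusted p = 0.0574). Nppa passed at 3.08 ± 0.72 (adjusted p = 6.46e-04) without the remote library of mouse 9180 and at 2.42 ± 0.67 (adjusted p = 0.00550) with mouse as a replicate block.

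In CKD mice the infarct had likewise gained matrix and immune transcripts and lost those of energy metabolism, while heart muscle transcripts were called lower as a list with 4 of 12 members passing. The infarct group includes the libraries of mice 9172 and 9179, with cardiomyocyte scores of 12.05 and 12.30. Structural matrix genes rose in 14 of 14 cases (median 2.48, adjusted p = 1.23e-06; Col1a1 4.50 ± 0.71 SE). With an estimated correlation this and each other list called in CKD mice had an adjusted p = 0.426 to 0.639. Higher members also numbered, for activated fibroblast markers, 11 of 12 (3.26; Lox, a collagen cross-linking enzyme, 4.70), for T and NK cell markers 9 of 9 (1.79; Lck 2.07), for MHC class II genes 7 of 7 (1.68; H2-DMb1 2.10) and for monocyte and neutrophil markers 7 of 12 (1.01; Ccr2 2.74). Oxidative phosphorylation genes fell in 13 of 15 cases (-0.98; Ndufb8 -0.89), fatty acid oxidation genes in 13 of 15 (-1.04; Hadha -1.02), cardiomyocyte markers in 4 of 12 (-1.07; Mb, myoglobin, -0.99) and endothelial markers in 8 of 10 (-0.56). Adjusted over the list alone, the counts were 14, 12, 9, 7, 7, 14, 14, 0 and 9. Nppa rose from 112 ± 83.5 CPM (SD, n = 8) to 1686 ± 1676 CPM (n = 7), a log2 fold change of 3.55 ± 0.72 (adjusted p = 5.54e-04). Spp1, osteopontin, rose by 8.86 ± 1.40 (SE), from 1.35 ± 0.87 CPM (SD, n = 8) to 843 ± 1992 CPM (n = 7). Its SD lies far above its mean in infarct tissue, so few libraries carried that mean. Myh6 passed at -0.96 (adjusted p = 0.0461) but not with mouse as a replicate block (-1.13, adjusted p = 0.0508) nor without the remote library of mouse 9179 (adjusted p = 0.0590). Ckm, muscle creatine kinase, passed at -0.95 (adjusted p = 0.0363) but not without that library (adjusted p = 0.0519).

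In total 19 lists were called in CKD mice, 14 higher and 5 lower, and 0 with an estimated correlation. Without the remote library of mouse 9179, the matrix protease (adjusted p = 0.0587), cardiomyocyte stress (0.0882), ion channel (0.0514) and cell cycle lists (0.124) were not called. By gene, edgeR called 6644 of 14770, 3654 higher and 2990 lower, and with mouse as a replicate block 7200. Among the smallest p were Gabra3 (2.25 ± 0.28), Ly9, a lymphocyte surface protein (4.04 ± 0.53), and Cd83 (1.55 ± 0.21), all higher, and Spry4, a growth factor signalling inhibitor (-0.79 ± 0.11), lower, each with an adjusted p = 7.16e-05. The control and CKD comparisons, which share no library, called 3262 genes higher in both against 1120.2 for independent calls, 2656 lower in both against 993.8, and 4 in opposite directions. Without the infarct libraries of CKD mice 9172 and 9179, edgeR called 9020 of 14933 genes in the CKD comparison, 4707 higher and 4313 lower.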

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

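Of the tests in this part, those of the CKD infarct libraries of mice 9172 and 9179 alone, of a swap within mouse 9179 and of residual blood, and the look into 1 drawn split, were chosen after the result was seen. So were the list fits without those infarct libraries or without the remote library of control mouse 9180, and the permutation tests of scores.

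Libraries that lie far from their group were searched for over 11 measures in 4 groups, 44 tests in all, and 3 values stood out. Chance alone gives about 1 in 20 of such tests, so this count is near that of chance. The remote library of control mouse 9180 had a cardiomyocyte score of 11.21 (next lowest 11.99) and Myh6 at 13.60 log2 CPM (next 14.82). Myh6 is a member of that score, so these values are not separate observations. The infarct library of CKD mouse 9179 had Col1a1 at 6.28 log2 CPM (next 10.71).

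The effect of CKD differed between infarct and remote tissue, by the camera test of the difference itself, for 10 gene lists. The median of the members' differences was 1.32 for cardiomyocyte markers, 0.25 for endothelial markers, 0.84 for ion channel and coupling genes, 1.17 for oxidative phosphorylation, 1.21 for fatty acid oxidation, 0.50 for glycolysis and 0.79 for hypoxia response genes. It was -1.29 for monocyte and neutrophil markers, -0.71 for structural matrix genes and -0.82 for cytokines. The monocyte and neutrophil difference was not tested without the infarct library of control mouse 9184, where that score was highest. None of the 10 was called with an estimated correlation (adjusted p = 0.528 to 0.832). Without the infarct libraries of CKD mice 9172 and 9179 the matrix list, of which 11 of 14 members had positive fitted fold changes, was at 0.15 (adjusted p = 0.865), and the cytokine, hypoxia and endothelial lists were not called (adjusted p = 0.113, 0.0684 and 0.375). Without the remote library of control mouse 9180 the glycolysis, hypoxia and endothelial lists were not called (adjusted p = 0.0584, 0.0731 and 0.0960), nor was the endothelial list without that of mouse 9179 (adjusted p = 0.101).

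The 2908 genes called between CKD and control infarcts may reflect a larger share of surviving myocardium in the CKD pieces. Slopes on the cardiomyocyte score fitted within the CKD infarct libraries alone gave the sign of the CKD difference for 97.3% of the 2903 called genes that are not themselves part of the score, and for 82.1% of the other genes above 1 CPM. Mice 9172 and 9179 had the highest scores among infarct libraries and also enter the CKD mean. No slopes were fitted without them. Slopes within the control infarct libraries gave the sign for 96.0% of called and 77.1% of other genes. Observed differences had a slope of 0.76 on those predicted from CKD libraries and 1.47 on those from control libraries. The predicted size thus depended on the group used. With the score as a covariate the calls ended because the effect shrank: the median size of the log2 fold change fell from 0.74 to 0.24, while the median standard error went from 0.20 to 0.18. The tables argue against the libraries of mice 9172 and 9179 as the whole source, since without them the median ratio to the full fold change was 0.750. Whether CKD left more muscle or a less mature scar in the infarct, or the pieces were taken nearer its border, stays open and untested.

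For the infarct library of CKD mouse 9179, which nearly lacked infarct transcripts, a swap with the remote library of the same mouse is argued against by that library's activated fibroblast score of 3.39, within the 2.07 to 4.96 of other remote libraries apart from that of control mouse 9180 (7.56) and below the 5.17 to 8.28 of other infarct libraries. A swap with the remote library of control mouse 9180, which has the opposite makeup, cannot be told apart from unusual tissue pieces, and no biological explanation was tested. Over 4 genes that mark a mouse in both regions, which are not independent replicates, the infarct library of mouse 9179 correlated at 0.217 with its own remote library and at up to 0.989 with those of other mice, whereas the remote library of mouse 9180 correlated best with its own infarct library, at 0.990 against up to 0.979. The first goes with a swap and the second against it, and such genes ranked a mouse's own remote library first in only 2 of 11 other mice, so they do not decide.

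In remote myocardium of CKD mice, the erythroid and MHC class II lists were called lower and the monocyte and neutrophil list higher, none of them with an estimated correlation (adjusted p = 0.254 to 0.348), and with mouse 9179 counted as control the exact permutation p of the monocyte and neutrophil score was 0.0641. Less residual blood of ordinary makeup would lower monocyte and neutrophil transcripts too, so the median of 0.82 of the monocyte and neutrophil list, itself part of the pattern, argues against it as the whole cause, while for the erythroid transcripts alone it stays open. The erythroid difference was not due to a single library, since its median stayed between -1.90 and -1.31 when each of the 14 was left out. Less epicardial tissue in the CKD pieces is argued against only weakly as the whole cause. With the mesothelial score as a covariate the MHC class II difference was -0.72 (SE 0.33), against -0.93 (SE 0.25) without. The remaining difference is not large against its standard error, and a mean of few markers may track such tissue imperfectly. This cause is therefore not excluded. An effect of CKD on circulating or resident immune cells, and on red cells, may remain as a hypothesis, found and tested on the same data.

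Other splits of the libraries were fitted to see whether regrouped animals give as many genes. For CKD in infarct tissue, 1 of 100 splits, the real one, reached 2908 genes. Chance is thus unlikely at a resolution of 1 in 100 but not excluded, and the highest other split called 2515. For CKD in remote myocardium, 2 of 100 splits reached 3 genes, and the other of them called 324, many times the real count, which points to a structure among the samples. It set 3 control libraries, that of mouse 9180 among them, and 3 CKD libraries against 3 and 5 others. Its calls, 313 higher and 11 lower in the 6 libraries, held 13 of 13 cell cycle genes, all higher there. Also higher there were 10 structural matrix, 6 activated fibroblast and 4 macrophage genes. This describes 1 drawn split and is not a test. For the difference of the effects, 100 of 100 reached the real count of 0, which any split does, so this says nothing about chance. For infarct against remote tissue, 1 of 100 splits reached 9437 genes in control mice (highest other 8255) and 1 of 100 reached 6644 in CKD mice (highest other 1977). These samples are paired by mouse, where the replicate block gave 9764 and 7200 genes. Of the drawn splits that part all 6 control pairs, 8 of 9 called 0 genes and the remaining split 8255, and the 3 that part all 7 CKD pairs called at most 1.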

How the results depend on the processing

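Among the alternatives in this part, those without the infarct libraries of CKD mice 9172 and 9179 and those without the remote library of control mouse 9180 for lists, differences and regions or together with the covariate were chosen after the result was seen. Where no cause is given below, the cause was not tested.

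The counts of the 2 region comparisons stayed within 1.5 times their value under the alternatives fitted for them. Those did not include the cardiomyocyte covariate or leaving out each library in turn. In remote myocardium the 3 genes became 1 without a filter, where more genes are tested, 97 with DESeq2, 5 with limma-voom, 1 in the fit of all 27 libraries, 0 with the cardiomyocyte covariate, 5 without mouse 9179, 1 with that mouse as control, and 0 with the covariate and without mouse 9180. Leaving out each library gave 1 to 6. In infarct tissue the 2908 genes became 1926 without a filter, 4557 with DESeq2, 5067 in the fit of all 27 libraries, 0 with the covariate and 0 without mice 9172 and 9179, where 4064 had an unadjusted p under 0.05. Leaving out each library gave 0 to 4651. The 0 genes of the difference became 600 with DESeq2 and 6 with limma-voom. With an estimated correlation 0 lists were called in each of the 5 comparisons. With fry the count was 0 in remote, 0 in infarct and 0 in the difference, and 25 between regions in control mice. With the covariate 3 lists were called in infarct tissue. The replicate block gave 9764 and 7200 genes between regions and 0 in the difference. Of the named genes its only lost call was Myh6 between regions in CKD mice, and it ended the call of the matrix protease list there (adjusted p = 0.0718). It also raised the lists called from 10 to 12 in the difference, from 16 to 19 in control and from 19 to 20 in CKD mice, let Nppa pass between regions in control mice (2.42, adjusted p = 0.00550), and changed no other call of a named gene.

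Signs that turned were these, none in a gene that had passed. In remote myocardium Myh6 went to -0.075 with the covariate and -0.056 with it and without mouse 9180, and Nppa to 0.055 with limma-voom and 0.10 with the covariate. Nppa in infarct tissue went to -0.36 with limma-voom, and leaving out each library gave -0.38 to 0.29, with negative values without control mouse 9171 (-0.055) or 9184 (-0.088) or CKD mouse 9176 (-0.14) or 9178 (-0.38). With the covariate in infarct tissue Apoe went to 0.073, Nppb to -0.15, Myh7 to -0.48, H2-Ab1 to 0.11 and Cdc20 to 0.080. In the difference Nppa went to -0.33 and Col1a1 to -0.87 with limma-voom, and Col1a1 to -0.51 with the replicate block and -0.30 without mouse 9180. Nppb between regions in control mice went to 0.18 with limma-voom.

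Medians of lists that turned in remote myocardium were oxidative stress genes with DESeq2 size factors (0.0023). With the covariate they were endothelial (0.010), macrophage (0.25), skeletal muscle (0.023), interferon (0.26), oxidative phosphorylation (-0.036), fatty acid oxidation (-0.34), cell cycle (0.32), glucocorticoid (-0.018) and oxidative stress genes (0.058). Without mouse 9180 they were macrophage (0.044), interferon (0.12), fatty acid oxidation (-0.13) and oxidative stress genes (0.015), and without mouse 9179 endothelial (0.017) and adipocyte markers (0.46). In infarct tissue with the covariate they were endothelial (-0.091), mural (-0.11), macrophage (0.19), T and NK cell (0.13), B cell (0.028), stress (-0.22), TGF-beta (0.076), MHC class II (0.050) and cell cycle genes (0.039), and without mice 9172 and 9179 mural markers (-0.073). In the difference they were atrial markers with the replicate block (0.16). Without mice 9172 and 9179 they were resting fibroblast (0.084), activated fibroblast (0.44), macrophage (0.083), B cell (0.014), matrix (0.15), TGF-beta (0.30), cell cycle (0.41), integrated stress (-0.0059) and osteochondrogenic genes (0.23). Without mouse 9180 they were atrial (0.31) and skeletal muscle markers (-0.16). Between regions they were cardiomyocyte stress genes in control mice without mouse 9180 (0.092), and in CKD mice glucocorticoid genes with DESeq2 size factors (0.021), without mouse 9179 (0.047) and without mice 9172 and 9179 (0.0027), and integrated stress genes with size factors (0.0097). Of these, oxidative phosphorylation in remote tissue, cell cycle in infarct tissue and matrix in the difference had been called.

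Upper-quartile scaling moved the infarct calls from 1883 higher and 1025 lower to 1632 and 1343. No scaling moved the median log2 fold change of all genes by over 0.1. Simulated changes of 1.5-fold were mostly missed in the difference of effects, so its count of 0 does not exclude them.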

Other observations

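The tests of this part were planned, and no hypothesis is put forward here. In infarct tissue of CKD mice, single members of further lists passed while the lists did not. Among oxidative stress genes, Sod2, the mitochondrial superoxide dismutase (1.40 ± 0.39 SE, adjusted p = 0.0346), Nqo1 (0.98 ± 0.30, adjusted p = 0.0383) and Cat, catalase (0.43 ± 0.13, adjusted p = 0.0403), rose. Among hypoxia response genes, the transferrin receptor Tfrc (1.62 ± 0.50), the prolyl hydroxylase Egln3 (1.06 ± 0.33) and the pyruvate dehydrogenase kinase Pdk1 (0.76 ± 0.24) rose (adjusted p = 0.0398, 0.0411 and 0.0404). Of the renin-angiotensin and TGF-beta genes, the angiotensin receptor Agtr1a rose (1.23 ± 0.33), while Tgfb3 (-1.30 ± 0.42) and Skil (-0.71 ± 0.17), an inhibitor of SMAD signalling, fell. Of cytokines, Il6 fell (-2.63 ± 0.80, adjusted p = 0.0394) and so did Ptgs2, cyclooxygenase 2 (-1.66 ± 0.55, adjusted p = 0.0475), and without control mouse 9184 they stood at -1.27 and -0.89 and did not pass. None of these was called with the cardiomyocyte score as a covariate, nor without control mouse 9171, 9182 or 9183 or CKD mouse 9172 or 9177, where 0 genes were called.

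Of 14 circadian clock genes 1 passed in each direction in infarct tissue, over all genes and adjusted over the list alone, and the list was not called (median 0.53, adjusted p = 0.0960). Arntl, the core clock activator, fell in CKD infarcts from 27.9 ± 8.45 CPM (SD, n = 6) to 10.7 ± 6.67 CPM (n = 7; log2 fold change -1.14, adjusted p = 0.0354), and the clock repressor Ciart rose (1.39, adjusted p = 0.0384). The 2 osteochondrogenic genes that passed, of 9 tested, were Col2a1 and Chad. Col2a1, a cartilage collagen, fell to a mean of 0.646 CPM from 11.9 CPM (log2 fold change -3.96, adjusted p = 0.0345), and Chad, a cartilage matrix protein, fell as well (-1.48, adjusted p = 0.0374). None of the 4 was called with the cardiomyocyte score as a covariate, nor without control mouse 9171, 9182 or 9183 or CKD mouse 9172 or 9177. Time of day of sampling is not in the labels.

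Myl7, an atrial myosin gene, varied within the remote groups, from 0.112 to 311.4 CPM in CKD and 0.428 to 221.5 CPM in control libraries. It stayed at 0.203 to 1.14 CPM in control infarct libraries. CKD infarct libraries ran from 0.499 to 171.3 CPM with a median of 1.12 CPM, and the highest value was that of mouse 9179. Myl7 was called higher in CKD infarcts (log2 fold change 6.03, adjusted p = 0.0376). The group mean behind this call, 25.5 ± 64.3 CPM (SD, n = 7), rested on the library of mouse 9179. The median, the mean and the test of a list differed in sign for 2 lists in remote tissue, among them adipocyte markers (median -0.02, test higher), for 2 in infarct tissue, atrial (0.94, test lower) and mural markers (0.20, test lower), for 1 in the difference of the effects, and for 3 and 2 between regions in control and CKD mice. None of these lists was called.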
